A study of Homo sapiens with 4 samples.

How the data were processed

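BRD8 ChIP-seq libraries from HCT116 and SW480 colorectal cancer cells were analysed, with 1 ChIP library per line. Per the labels' protocols, fixation lasted 10 minutes in formaldehyde at 1%, and micrococcal nuclease fragmented the chromatin. BRD8 was precipitated with 2 µg of a polyclonal antibody, libraries were made from 1 ng of DNA, and reads were paired with 150 bp at each end. An input library accompanied each line, and its own signal was not analysed here.

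Per the submitters' processing notes, reads were processed with Trimmomatic 0.33 and Bowtie2 2.4.1, and MACS2, a peak caller, and deepTools were used, with the GRCh38 build. The MACS2 and deepTools versions, the read filters and the treatment of duplicate reads are not given in the sources used here. The deposited lists hold 1 set of peaks per ChIP library, so peaks were not pooled over samples, and the smallest −log10 q in each list corresponds to a q threshold of 0.05. The deposited fold enrichment is the ratio of ChIP signal to the caller's local background at the summit, with 1 added to each. The deposited −log10 p-value and −log10 q-value belong to the same summit. The deposited score is 10 times the −log10 q, cut to a whole number, for 99.8% of HCT116 and 99.98% of SW480 peaks. The deposited summit offset gives the summit position in bp from the region start. Fold values depend on the depth and input of each library, so peaks were ranked by them within a list. Values of the lines are shown side by side, and the ratios at shared genes describe these libraries.

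The lists give no read totals. MACS2 fold and p follow from the summit pileup and the local background, so both were solved for each peak by scanning pileups up to 2999 fragments, with a relative tolerance of 0.0001 on the p. This succeeded for 99.996% of HCT116 and 99.99% of SW480 peaks. The median pileup was 24 fragments in HCT116 and 26 in SW480, and the lowest was 12 and 13. The lowest background, which is set by the coverage of the whole ChIP library, was 3.75 and 4.09. Of the backgrounds above that lowest level, 48.4% and 46.9% fell on multiples of 0.574 and 0.865. Each step was searched for to make this share largest. The 0.2% that chance gives for a fixed step is therefore not a strict reference. If that step is the weight of 1 input fragment, the inputs held 1.74 and 1.16 times as many fragments as their ChIP libraries.

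Regions on chromosomes 1 to 22 and X were kept. Chromosome Y was left out, as were 8 HCT116 and 68 SW480 peaks on other contigs, which are given among the closing observations. Positions are 1-based GRCh38 coordinates. Genes came from a RefSeq table of GRCh38.p14 with 59094 genes on these chromosomes, 19970 of them protein-coding. That table holds gene starts, ends and types, without strand, transcripts or sequence. The planned promoter class was therefore replaced by a summit within 1 kb of either end of a gene, and exons, introns and motifs were not analysed here. Of other summits, those between the ends of a gene were called inside a gene and the rest outside genes. A gene's value is the peak of highest fold among those within 1 kb of either end.

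Shares are given with 95% Wilson intervals, which describe counting error within these libraries. Each share was set beside 100 random placements of the regions on the same chromosomes, from position 1 to the last annotated gene end, with assembly gaps not excluded. Overlap between lines needed 1 bp and was also set beside 100 shifts of 20 to 200 kb. The number of genes bound in both lines was compared with the product of the 2 counts divided by all genes. No test across genes was made, because genes are not replicates. Ratios of pileup and background at shared genes used the 1349 genes with a peak in both lines that ranked among the top 1000 genes of either line by −log10 q, with intervals from 1000 bootstrap draws over genes, which cover the spread among genes. Ratios of chromosome shares have 95% counting intervals on the log scale.

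For each of 24 gene lists, the count of members with a gene-end peak was ranked among 10000 random lists of the same size drawn from all protein-coding genes. The percentile describes these libraries and is not a test between cells. Matching the random lists on GC content was planned and needs sequence, so the unmatched draw that the plan provided was used. All listed genes were found in the annotation. The result of 1 list is not reported here.

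The gene lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule took, per line, the 10 genes of highest gene-end fold, and the 10 of highest −log10 q with no region of the other line within 5 kb. It further took every TIP60/NuA4 and replication licensing gene. Of each other list it took the 2 members of highest HCT116 fold and up to 2 per line bound in that line alone. It also took the 5 peaks of highest fold away from gene ends in each line. Alternatives covered the peak threshold, equal numbers of peaks, the distance from gene ends, the gene types and the definition of overlap. Others were added later and are identified as such.

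The procedures were tested on simulated data. Pileup was recovered exactly for 100% of 2000 simulated peaks. For the overlap of SW480 with HCT116 over 12874 regions, 40% planted overlap gave 40.6% and none planted gave 1.16%. For the HCT116 gene-end share over 22303 regions, 30% planted gave 34.6% and none planted gave 6.70%. Of 200 simulated lists at the SW480 gene rate, all planted ones passed the 95th percentile, as did 5.5% of the unplanted ones. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for the plots.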

Results

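BRD8 is a bromodomain protein and a subunit of the TIP60/NuA4 histone acetyltransferase complex, a large chromatin-modifying machine built around the acetyltransferase KAT5. The series asked where BRD8 sits on the genome of colorectal cancer cells. It used HCT116 and SW480, established human colorectal cancer lines grown as monolayers. Each line contributed 1 BRD8 chromatin immunoprecipitation sequencing (ChIP-seq) library and 1 input library, 4 libraries in all. The peak list of each ChIP library was analysed here. With 1 ChIP library per line, no difference between the lines has a replicate check, and intervals on shares cover counting error only. The HCT116 list held 22303 peak regions on chromosomes 1 to 22 and X, with a median width of 596 bp and 19.9 Mb covered. The SW480 list held 12874 regions with a median width of 394 bp and 7.05 Mb covered. Median fold enrichment was 3.70 in HCT116 and 3.34 in SW480. The fold and q values are the authors' own, and fold levels depend on the depth and input of each library.

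BRD8 peaks gathered at the ends of genes in both lines. In HCT116, 47.1% of peak summits (95% Wilson interval 46.5 to 47.8) lay within 1 kb of an annotated gene end, and random placements of the same regions gave 6.83%. In SW480 the share was 40.3% (39.5 to 41.2), and random placements gave 6.49%. The excess over random placement was 6.90-fold in HCT116 and 6.21-fold in SW480. Ends of protein-coding genes alone took 39.96% of HCT116 summits and 34.04% of SW480 summits, against 2.86% and 2.59% at random. Summits elsewhere inside genes made up 38.3% in HCT116 and 41.6% in SW480, both below the random shares of 52.3% and 52.6%. Summits outside genes made up 14.5% and 18.1%, against 40.9% at random in each line.

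**Figure D1:**
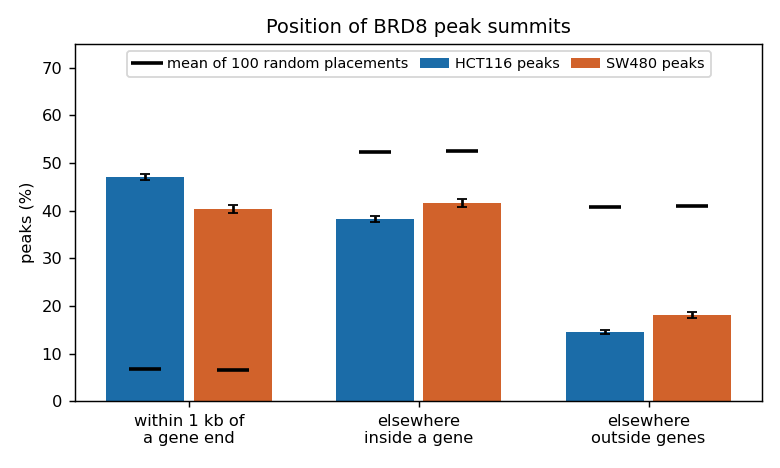
Share of BRD8 peak summits (%) by position for HCT116 (22303 peaks) and SW480 (12874 peaks), with bars for the observed share, error bars for 95% Wilson intervals and black marks for the mean of 100 random placements. Gene ends held 47.1% and 40.3% of summits, and the random marks there lie at 6.83% and 6.49%.

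Gene-end binding was most frequent among the strongest peaks. When each list was divided into 10 equal groups by −log10 q, 84.9% of summits in the strongest HCT116 group (83.4 to 86.4) lay at gene ends. In the weakest group the share was 26.4% (24.6 to 28.2). In SW480 the share went from 74.2% (71.8 to 76.5) in the strongest group to 31.9% (29.4 to 34.5) in the weakest. Genes with an end peak nearly always had it at 1 end alone. Of 14315 protein-coding genes of at least 10 kb, 6801 had an end peak in HCT116, and 96.5% of these had it at 1 end alone. In SW480 the numbers were 3506 genes and 98.3%. A peak at 1 end alone is also frequent when few ends carry a peak. No chance level was computed for these shares, so they do not measure a preference for 1 end. The annotation used gives no strand, so the 5′ and the 3′ end of a gene were not told apart.

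**Figure D2:**
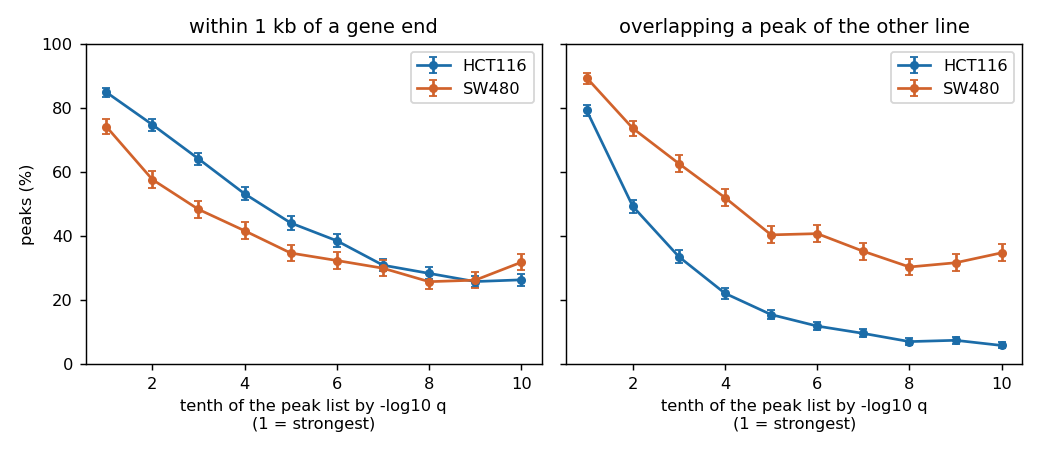
Share of peaks (%) within 1 kb of a gene end (left) and share overlapping a peak of the other line (right), for 10 equal groups of each list ordered by −log10 q with 1 the strongest; error bars are 95% Wilson intervals. In the strongest group 84.9% of HCT116 and 74.2% of SW480 peaks lay at gene ends, and 79.2% and 89.4% overlapped the other line.

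The highest gene-end enrichments in HCT116 were at genes of varied function. HNRNPA1, an abundant pre-mRNA-binding protein on chromosome 12 (54280726 to 54287087, GRCh38), had a fold of 28.3. GABPB1, a subunit of the GABP transcription factor, had a fold of 28.1, and ZNF598, a ubiquitin ligase that acts on stalled ribosomes, also had 28.1. DDX42, an RNA helicase on chromosome 17 (63773800 to 63819317), had 27.6, as did RBM3, a cold-inducible RNA-binding protein on the X chromosome. EIF3E, a translation initiation factor subunit, had 26.5. GART and PPAT, enzymes of purine synthesis, had 25.1 and 24.9. MGME1, a mitochondrial DNA exonuclease, had 23.9, and METTL1, a tRNA methyltransferase, had 23.4.

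In SW480 the highest gene-end fold was at DDX42, at 16.3. IARS1, the cytosolic isoleucyl-tRNA synthetase on chromosome 9 (92210207 to 92293697), followed at a fold of 16.3. GDI2, a regulator of Rab GTPases, had 12.8, and YARS1, the tyrosyl-tRNA synthetase, had 12.7. RBM3 had 12.4, NRDC, a metalloprotease, 12.2, and CHMP4C, an ESCRT-III protein of cell division, 11.6. MRPS18B, a mitochondrial ribosomal protein, had 11.4, SLC25A32, the mitochondrial folate carrier, 11.2, and DCAF17 11.1. All of these SW480 genes also had a gene-end peak in HCT116, with folds from 6.66 at CHMP4C to 27.6 at DDX42 and RBM3.

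Some of the strongest BRD8 peaks lay away from gene ends. The highest fold of the HCT116 list, 41.3, was inside MIR17HG, the host gene of the miR-17 microRNA cluster, on chromosome 13 (91346578 to 91352320, GRCh38). A SW480 peak overlapped it at a fold of 10.5. Other strong HCT116 sites lay inside CACNA1A on chromosome 19 (13334633 to 13336460, fold 29.3), inside the long noncoding RNA gene LNCOC1 on chromosome 8 (142716167 to 142718903, fold 24.99) and inside TFAP4 on chromosome 16 (4270169 to 4274454, fold 23.3). The TFAP4 summit lay 1519 bp from the nearest end of that gene, which encodes a basic helix-loop-helix transcription factor. A narrow site on the X chromosome (134885453 to 134885757), 2023 bp from MOSPD1, had a fold of 27.6 in HCT116, and the overlapping SW480 peak had 24.6. The 5 strongest such sites of SW480 all lay outside genes. They were on chromosome 5 (49601460 to 49603001, fold 39.2, and 49656745 to 49659057, fold 28.5), chromosome 16 (46390382 to 46391215, fold 30.1, and 46394188 to 46394933, fold 27.1) and chromosome 4 (49657487 to 49657781, fold 29.5). The nearest gene ends were from 67886 bp (SNX18P25, chromosome 4) to 794087 bp (EMB, chromosome 5) away. Summit pileups at these 5 sites ran from 137 to 758 fragments, against a median of 26 for the SW480 list. No filter for repeated sequence was applied here, so mapping artifacts at these sites were not told apart from binding.

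Comparing the lines asks which BRD8 sites are shared between these cancer cells. Of the SW480 peaks, 49.1% (48.3 to 49.99) overlapped an HCT116 peak by at least 1 bp, and of the HCT116 peaks 24.2% (23.6 to 24.8) overlapped a SW480 peak. Random placement gave 1.15% and 0.67%, and moving each region by 20 to 200 kb gave 2.38% and 1.40%. Sharing was concentrated at gene ends. There, 84.1% (83.1 to 85.1) of SW480 peaks and 36.1% (35.2 to 37.1) of HCT116 peaks overlapped the other line. Inside genes the shares were 28.4% and 14.1%, and outside genes 18.9% and 12.05%. Peaks found in both lines had the higher −log10 q. Their median was 14.05 in HCT116 and 5.98 in SW480, against 4.56 and 3.42 for peaks of 1 line alone. Median folds were 5.31 for shared HCT116 peaks and 3.46 for the rest, while in SW480 they were 3.3005 and 3.34.

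Among the 1000 peaks with the highest −log10 q, 90.0% (88.0 to 91.7) of HCT116 and 90.5% (88.5 to 92.2) of SW480 peaks overlapped a peak of the other line. The strong peaks seen in 1 line alone differed in place. Of the 100 such HCT116 peaks 73.0% lay at gene ends, and of the 95 such SW480 peaks 12.6% did. Each peak was compared with the whole list of the other line. That list has gene-end peaks at 8791 genes in HCT116 and 4413 in SW480, so a SW480 gene-end peak had more to overlap. The SW480 peaks also include the chromosome 4 and 5 sites above, which were not filtered for repeated sequence.

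Gene by gene, HCT116 contained nearly the whole SW480 set. Of 19970 protein-coding genes, 8791 (44.0%, 43.3 to 44.7) had a gene-end peak in HCT116 and 4413 (22.1%, 21.5 to 22.7) in SW480. Both lines had a peak at 4051 genes, 2.09 times the 1943 that independent sets would share. These made up 91.8% of the SW480 genes and 46.1% of the HCT116 genes. A peak in HCT116 alone was found at 4740 genes and a peak in SW480 alone at 362. Because each list ends at a q threshold, absence from a list does not show absence of binding.

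The HCT116 gene-end peaks with the highest −log10 q and no SW480 region within 5 kb of the gene end were also at genes of varied function. MRPL42, a mitochondrial ribosomal protein, had a fold of 16.4 and a −log10 q of 100.1. CDCA2, which targets a phosphatase to mitotic chromatin, had a fold of 16.2, and PSMC4, a proteasome ATPase, 14.2. TBCB, a tubulin-folding cofactor, had 13.3 from a peak that it shares with the adjoining gene POLR2I. MRPS21 had 12.4, PLK4, the kinase of centriole duplication, 12.2, and CALM3 12.5. EEF1D had 8.30, QTRT1 12.3 and NSUN4 13.9. The corresponding SW480 genes had varied functions. IFRD1, on chromosome 7 (112423174 to 112477203), had a fold of 8.56 and a −log10 q of 26.0. VLDLR, a lipoprotein receptor, had a fold of 5.27 and a −log10 q of 20.9. DYNLRB2, RGS14, ZNF718, CD27, MAP1B, INSIG2, BACE2 and SPIN2B completed the SW480 list, with ZNF718 at a fold of 4.79.

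At genes bound in both lines the ChIP signal differed less between the lines than the local background did. The summit pileup, in overlapping fragments, was recovered from the fold and p values, with the local background estimated by the peak caller. Over 1349 strong shared genes the median pileup was 68 in HCT116 and 57 in SW480, and the median ratio of SW480 to HCT116 was 0.864 (bootstrap interval 0.840 to 0.892). The median background was 6.31 in HCT116 and 12.1 in SW480, with a ratio of 1.84 (1.76 to 1.93). The fold ratio was 0.492 (0.473 to 0.510). These ratios come only from genes with a called peak in both lines, so they depend on a SW480 pileup high enough to be called. The pileups were not scaled to the coverage of each library. At BRD8 itself, whose peak is shared with the adjoining gene KIF20A, the pileup was 51 in HCT116 and 53 in SW480, while the background was 5.36 and 18.2, and the fold 8.18 and 2.82. At HNRNPA1 the pileups were 179 and 146 and the backgrounds 5.36 and 26.8. At MCM7 the pileups were 89 and 64 and the backgrounds 6.88 and 23.4. The median background at SW480 gene-end peaks was 10.4, against 5.19 at peaks elsewhere inside genes. In HCT116 the medians were 5.79 and 5.16. Across the 4051 shared genes the ranks of fold correlated with a Spearman rho of 0.364, and those of −log10 q with a rho of 0.521. These are correlations across genes, which are not independent replicates.

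BRD8 occupied genes of its own complex. Of 18 subunits of TIP60/NuA4, 16 had a gene-end peak in HCT116 and 11 in SW480. Random lists of 18 protein-coding genes had a median of 8 and 4, and 0 and 5 of 10000 random lists reached the observed counts. The random lists draw on all protein-coding genes, including groups nearly free of peaks, and the excess was not particular to this complex. Bound shares were 88.9% and 61.1% here. They were 96.4% and 82.1% for core spliceosome genes, and 95.2% and 84.5% for ribosomal protein genes. All 11 SW480 genes also had a HCT116 peak. MORF4L2 had the highest HCT116 fold at 12.01, followed by ING3 at 10.4, YEATS4 at 10.1 and ACTL6A at 8.41. In SW480 the folds were 4.49, 5.11, 3.53 and 3.28. MORF4L1 had 7.99 and 5.68, KAT5 5.07 and 3.65, MBTD1 5.55 and 2.80, EPC1 4.42 and 4.70, RUVBL1 4.38 and 3.77, and MEAF6 4.22 and 3.83. DMAP1, EPC2, MRGBP, RUVBL2 and VPS72 had a peak in HCT116 alone, with folds from 4.31 at DMAP1 to 5.16 at MRGBP. EP400 and TRRAP, the largest subunits, had no gene-end peak in either line. In HCT116 each had 1 peak inside the gene, 1408 bp and 1162 bp from an end.

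Genes of DNA replication licensing, which load and fire the replicative helicase at origins, were bound to a similar extent. Of 28 members, 26 had a gene-end peak in HCT116 and 18 in SW480, and random medians were 12 and 6. In each line 0 of 10000 random lists reached the count. MCM3, a helicase subunit on chromosome 6 (52264015 to 52284742, GRCh38), had the highest folds, 13.5 and 8.97. MCM7 had 11.4 and 2.66, DBF4, the activator of the kinase CDC7, 10.9 and 4.28, and MCM2 10.2 and 7.55. ORC6 had 9.24 and 3.02, TICRR 8.61 and 4.57, and GINS1 8.34 and 2.67. MCM4, MCM6, CDC7, CDC45, GMNN, ORC2, ORC3, ORC4, ORC5, TOPBP1 and WDHD1 were also bound in both lines. MCM5, CDT1, CDC6, GINS2, GINS3, GINS4, MCM10 and RECQL4 had a peak in HCT116 alone, with MCM5 highest at 8.46. ORC1 and MCMBP had no gene-end peak in either line. In HCT116 their strongest peaks inside the gene lay 5423 bp and 1556 bp from an end, and in SW480 4537 bp and 1803 bp.

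**Figure D3:**
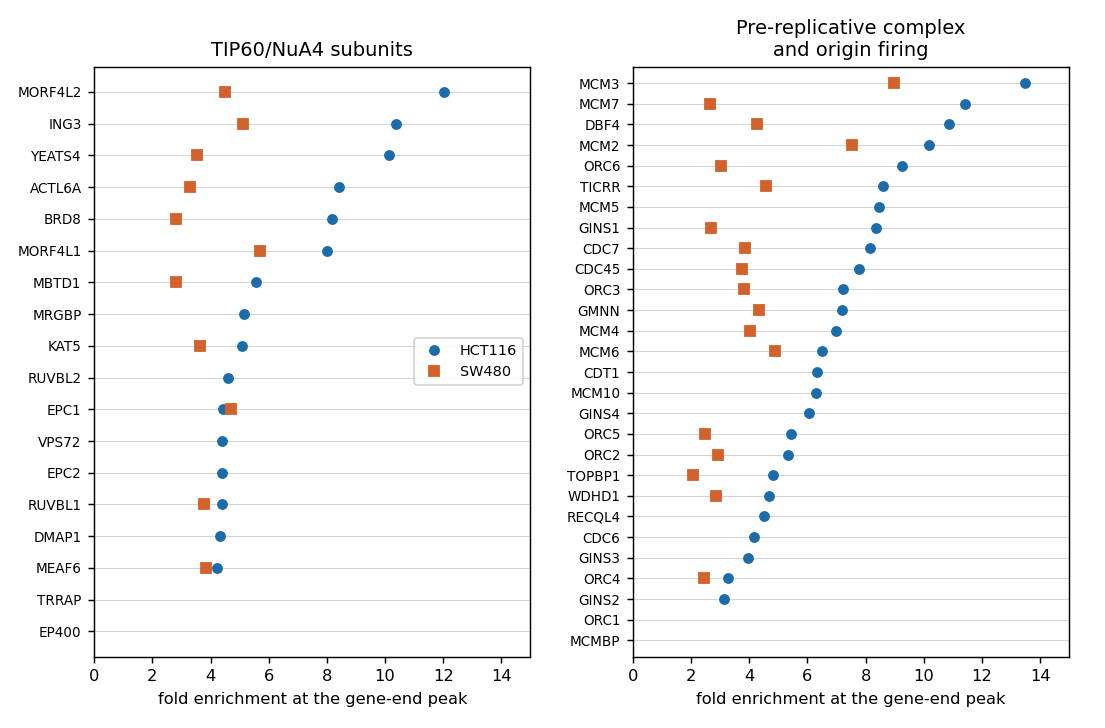
Fold enrichment at the gene-end peak for each TIP60/NuA4 subunit (left) and each replication licensing gene (right), with circles for HCT116 and squares for SW480; a gene without a symbol of a line had no gene-end peak in that line. TIP60/NuA4 genes with a peak number 16 in HCT116 and 11 in SW480, and licensing genes 26 and 18.

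Cell cycle and DNA repair genes carried BRD8 in both lines. Of 26 G1/S genes, 22 had a gene-end peak in HCT116 and 15 in SW480. E2F3, a transcription factor of S-phase entry, had folds of 11.2 and 3.61, and TYMS, thymidylate synthase, 11.03 and 3.11. CCNE1 and CCND3, which encode cyclins, had a HCT116 peak alone at 7.51 and 5.98. Of 25 G2/M genes, 24 and 18 were bound. AURKA, a mitotic kinase, had 14.4 and 5.37, and CENPF, a kinetochore protein, 14.3 and 3.68. BIRC5 and CCNB2 had a HCT116 peak alone at 6.91 and 8.83. Of 26 homologous recombination and damage signalling genes, 24 and 17 were bound. MDC1, a scaffold of the DNA damage response, had 13.4 and 8.31, and ATM, its upstream kinase, 12.1 and 4.58. FANCI and BRIP1 had a HCT116 peak alone at 6.78 and 5.65. For each of these 3 lists 0 of 10000 random lists reached the count in either line.

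Genes of ribosomes, splicing and the proteasome were bound in both lines. Of 84 cytosolic ribosomal protein genes, 80 had a gene-end peak in HCT116 and 71 in SW480, against random medians of 37 and 18. RPL5 had folds of 21.4 and 5.58 and RPL24 20.9 and 4.57, while RPL7 and RPL8 had a HCT116 peak alone at 10.4 and 8.10. Of 28 core spliceosome genes, 27 and 23 were bound. SNRPF had 15.4 and 2.08 and SNRPB 13.5 and 3.90, and SF3B4 and PRPF31 were bound in HCT116 alone. Of 26 ribosome biogenesis genes, 25 and 20 were bound. DDX21, a nucleolar helicase, had 19.0 and 5.25, and NOLC1 15.1 and 8.495, while RRP12 and BOP1 were bound in HCT116 alone. Of 39 proteasome genes, 33 and 21 were bound. PSMA3 had 12.6 and 5.50, PSMC4 and PSMD8 were bound in HCT116 alone and PSMD10 in SW480 alone at 4.47. For these 4 lists 0 of 10000 random lists reached the count in either line.

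Genes of complex I of the respiratory chain, the transcription machinery and the histones were also bound. Of 36 nuclear-encoded NADH dehydrogenase genes, 32 were bound in HCT116 and 14 in SW480, and 0 and 163 of 10000 random lists reached these counts. NDUFS1 had folds of 13.8 and 6.46 and NDUFB9 9.74 and 4.96. NDUFS5 and NDUFB5 were bound in HCT116 alone and NDUFS4 in SW480 alone. Of 42 RNA polymerase II and Mediator genes, 33 and 15 were bound, and 0 and 319 random lists reached these counts. The SW480 count did not stay above the 95th percentile with stricter peaks, with 13 at the 93.9 percentile for a −log10 q of at least 2 and 8 at the 79.6 percentile for at least 5. POLR2I and POLR2D had the highest HCT116 folds at 13.3 and 9.84 and no SW480 peak. Of 69 replication-dependent histone genes, 39 and 24 were bound, at the 98.2 and 99.3 percentiles. With equal numbers of peaks the HCT116 count was 31, at the 89.9 percentile. The SW480 count was 19 (percentile 90.7) at a −log10 q of at least 2 and 9 (36.5) at 5 or more. H2AC12 and H2BC12 share 1 peak with folds of 8.37 and 5.90, and neighbours such as H2AC11 and H2BC11 also share a peak, which the random lists do not reflect. H3C12 and H4C3 were bound in HCT116 alone, and H3C8 and H2BC6 in SW480 alone. Reads from these near-identical genes can be shared between copies, so their assignment is uncertain.

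**Figure D4:**
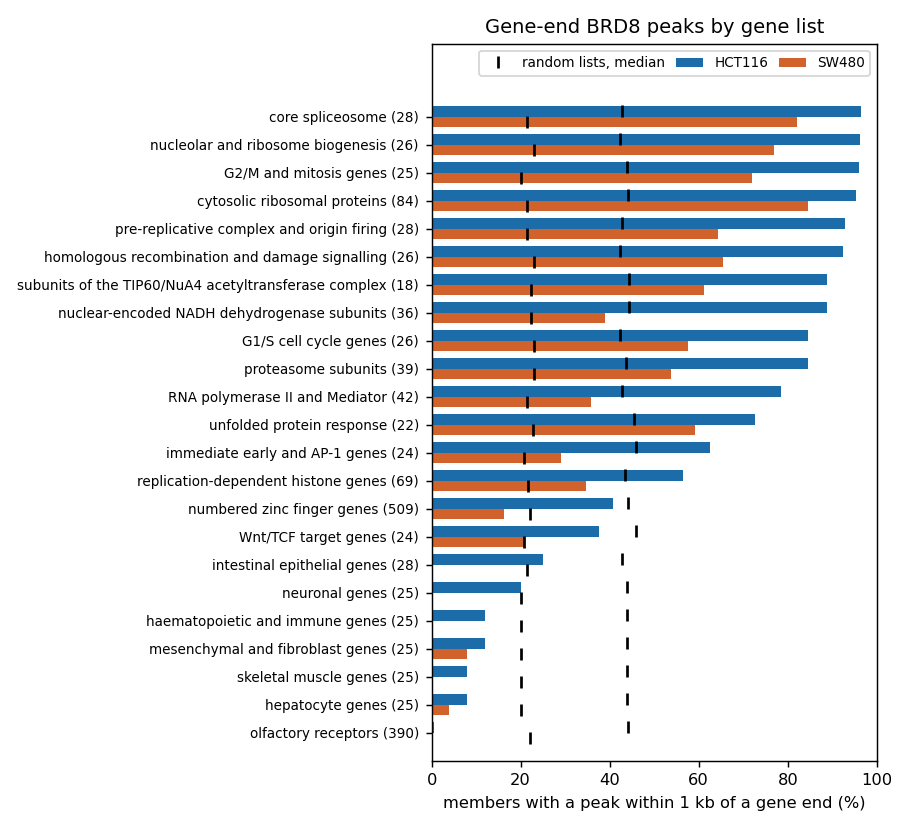
Members of 23 gene lists with a BRD8 peak within 1 kb of a gene end (% of members measured, number of members in parentheses), with bars for HCT116 and SW480 and black ticks for the median of 10000 random lists of the same size. Occupancy runs from 27 of 28 core spliceosome genes in HCT116 to 0 of 390 olfactory receptor genes in SW480.

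Unfolded protein response genes carried BRD8 in both lines. Of 22 unfolded protein response genes, 16 were bound in HCT116 and 13 in SW480, at the 99.6 and 99.995 percentiles of random lists. ATF4, a stress transcription factor, had folds of 12.5 and 9.14, and CHAC1, which degrades glutathione, 10.9 and 8.56. CANX and DNAJC3 were bound in HCT116 alone. Of 24 immediate early and AP-1 genes, 15 and 7 were bound, at the 95.98 and 79.7 percentiles. With equal numbers of peaks the HCT116 count was 13, at the 94.9 percentile. IER3 had 7.44 and 3.70 and JUN 5.65 and 2.72, FOS and JUNB were bound in HCT116 alone, and FOSL2 and PHLDA1 in SW480 alone.

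Wnt target genes were bound near the random level at gene ends, and intestinal and mesenchymal genes less often. Of 24 Wnt/TCF target genes, 9 were bound in HCT116 and 5 in SW480, at the 26.8 and 46.4 percentiles. ZNRF3, a Wnt receptor ligase, had folds of 6.81 and 2.01, SOX4 and AXIN2 were bound in HCT116 alone, and SP5 in SW480 alone. Of 28 intestinal epithelial genes, 7 and 0 were bound, at the 2.06 and 0.045 percentiles. The HCT116 peaks included EPCAM, an epithelial adhesion molecule, at 4.91, CLDN4 at 3.92 and CLDN7 at 3.45. Of 25 mesenchymal and fibroblast genes, 3 and 2 were bound, at the 0.02 and 3.52 percentiles. The SW480 percentile was 5.435 among random lists matched on gene length and nearby gene ends. SNAI1 had 7.69 and 3.65, and ZEB1 5.08 in HCT116 alone.

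Genes of other tissues were largely free of gene-end peaks, below the random medians of 11 in HCT116 and 5 in SW480 for lists of 25. Of 25 haematopoietic and immune genes, 3 and 0 were bound, with CD68 at 3.57, CD8A at 3.23 and TYROBP at 3.10. Of 25 hepatocyte genes, 2 and 1 were bound, TAT at 5.38 in HCT116 alone and TF at 4.82 and 2.08. The TF peak is also the gene-end peak of the neighbouring licensing gene TOPBP1. Of 25 neuronal genes, 5 and 0 were bound, with TUBB3 at 5.92 and DLG4 at 4.10. Of 25 skeletal muscle genes, 2 and 0 were bound, ACTN3 at 5.19 and TNNT1 at 4.24. Of 390 olfactory receptor genes, 2 and 0 were bound, OR51B5 at 4.98 and OR52D1 at 2.67. Genes with numbered ZNF symbols, which include most KRAB zinc finger genes, are not a tissue group and were bound nearer the random level. Of 509 such genes, 207 and 83 were bound, against random medians of 224 and 112, at the 6.13 and 0.040 percentiles. For HCT116 the percentile was 0.010 among random lists matched on gene length and nearby gene ends, and 1.29 with equal numbers of peaks. ZNF598 and ZNF460 had the highest HCT116 folds of that group at 28.1 and 20.2. ZNF326 and ZNF696 were bound in HCT116 alone, and ZNF718 and ZNF888 in SW480 alone.

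The lists differed most in their spread over chromosomes at chromosome 7. It held 1891 SW480 peaks, 14.7% of the list, and 1114 HCT116 peaks, 4.99%, a ratio of shares of 2.94 (2.74 to 3.16). The excess was larger away from gene ends, where the ratio was 3.7997 (3.48 to 4.15), than at gene ends, where it was 1.44 (1.26 to 1.64). A stretch from 76 to 96 Mb alone held 880 SW480 peaks and 96 HCT116 peaks. Chromosomes 19 and 4 stood at the other extreme, with ratios of 0.422 (0.373 to 0.477) and 0.450 (0.398 to 0.509). With peaks of −log10 q of at least 5, the chromosome 7 ratio was 1.89 (1.68 to 2.12).

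**Figure D5:**
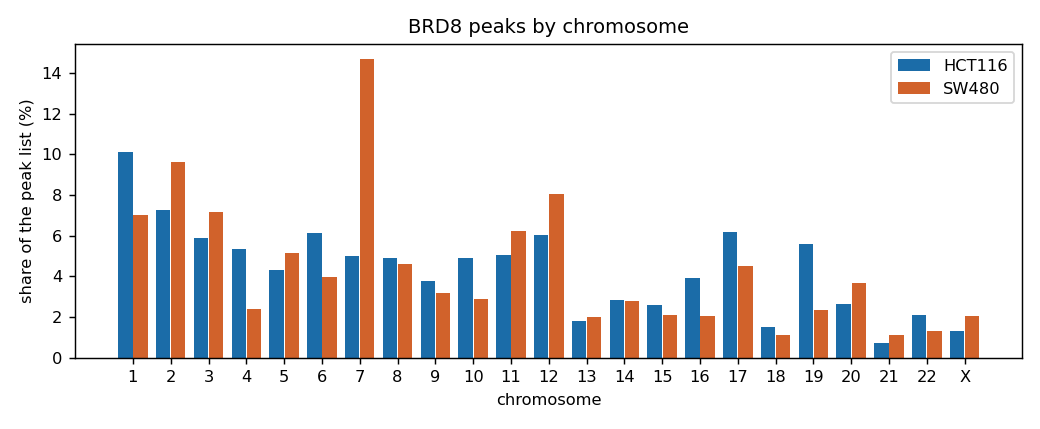
Share of each peak list (%) on chromosomes 1 to 22 and X, with bars for HCT116 (22303 peaks) and SW480 (12874 peaks). Chromosome 7 held 14.7% of the SW480 list and 4.99% of the HCT116 list.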

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

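No test bears on the results in this part, which are given as values. Peaks outside the numbered chromosomes, X and Y were not part of any comparison. HCT116 had 8 such peaks on 6 contigs and SW480 had 68 on 23 contigs, although the SW480 list was the shorter one. They stand out because any peak there is signal in data outside the main measurement, and no control list was analysed here to set a level for them.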

How the results depend on the processing

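The alternatives without dense 1-Mb windows, with summits anywhere in the gene, with random lists matched on gene length and neighbours, and with equal numbers of genes were chosen after seeing the data. Of the alternative values for the main results 58 stayed within counting error, or within 1.5 times for counts, and 32 moved. Among the gene lists some directions reversed. HCT116 histone genes went from 39 against a random median of 30 to 12 against 15 with equal numbers of genes. SW480 histone genes went from 24 against 15 to 9 against 10 at a −log10 q of at least 5. Raising the threshold to a −log10 q of at least 2 gave gene-end shares of 48.3% (HCT116) and 41.3% (SW480) and a SW480 overlap of 50.3%. At 5 it left 12045 and 5396 peaks, gene-end shares of 62.7% and 54.4%, overlaps of 25.6% and 62.7%, 2897 SW480 genes, 2638 genes in both lines and a chromosome 7 ratio of 1.89. With equal numbers of peaks the HCT116 gene-end share was 60.9%, the overlaps were 36.3% and 43.9%, and 559 genes were bound in SW480 alone. Without windows of 30 or more peaks away from gene ends, the gene-end shares were 50.7% and 45.6% and the overlaps 25.4% and 52.9%. Within 500 bp of a gene end lay 34.5% and 29.2% of peaks, with 565 genes in SW480 alone, and within 2500 bp 63.1% and 52.9%. Ends of protein-coding genes held 39.96% and 34.04%. A reciprocal overlap of 50% left 7.98% and 13.8% shared, and summits within 200 bp 15.8% and 27.4%. The shifts with distance and with the overlap rule follow from a wider or stricter definition. Higher thresholds and equal numbers of peaks drop weak peaks, which lay less often at gene ends, so the gene-end shares rise. The dense windows left out were chosen for peaks away from gene ends, which favours a higher gene-end share. The cause of the other shifts was not tested. Using −log10 q in place of fold gave a rho of 0.521. Of 230 fold values at genes taken by the naming rule, 48 had no peak within 500 bp and 12 came from another peak there. At a −log10 q of at least 5, 19 of them had no peak. Counts of list members moved for 14 lists with equal numbers of genes, which cut the HCT116 genes from 8791 to 4413. They moved in 12 cases at a −log10 q of at least 5, 10 with summits anywhere in the gene, 9 within 2500 bp and 2 with equal numbers of peaks. Among 2000 random lists, the percentile of HCT116 immediate early genes was 90.7 at a −log10 q of at least 5 and 79.2 with equal numbers of genes, and in SW480 it was 97.7 within 2500 bp. HCT116 histone genes fell to 88.8 and 17.0 under the first 2 of these. With summits anywhere in the gene the percentiles were 95.4 (SW480 Wnt targets), 9.53 (HCT116 intestinal genes), 14.5 (SW480 mesenchymal genes), 75.7 and 92.6 (histone genes, HCT116 and SW480) and 87.1 (SW480 polymerase II and Mediator). No paired analysis was possible because each line has 1 ChIP library. Motif alternatives, any annotated transcription start and GC-matched random lists were not run, since sequence and transcripts were not used here. Coverage limits the weak sites: the lowest called summits held 12 and 13 fragments.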

Other observations

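The tests of copy gain and of library coverage in this part were chosen after their results had been seen, and the other tests after their patterns were seen and before their own outcomes. The genes and regions named here were also chosen after their values were seen. Long runs of BRD8 peaks lay inside single genes, with unequal numbers in the lines. Some of these runs were part of wider stretches dense in peaks. In HCT116, PCDH7, a protocadherin on chromosome 4, held 113 peaks and none in SW480. PDE4B, a cAMP phosphodiesterase, held 39 against 0, and MET, a receptor tyrosine kinase, 23 against 0. NSMCE2 held 53 against 11, PHLDB2 44 against 11 and VTI1A 43 against 1. In SW480, SOX5, a transcription factor gene on chromosome 12, held 120 peaks and none in HCT116. COG5 held 49 against 0, MAGI2 48 against 0, SEMA3A, an axon guidance ligand, 39 against 2, and CDK6, a G1 cyclin-dependent kinase, 29 against 12. MAGI2, SEMA3A and CDK6 lie in the chromosome 7 stretch from 76 to 96 Mb, which held 880 SW480 peaks. MAGI2 spans 1437 kb, with 3.34 SW480 peaks per 100 kb. On chromosome 12 the windows from 22 to 23 Mb and from 26 to 27 Mb, outside SOX5, held 46 and 56 SW480 peaks. In the window of chromosome 12 from 23 to 24 Mb, which includes part of SOX5, 108 SW480 peaks had a median fold of 3.54 and a median background of 4.09, the lowest level of that list. The densest SW480 window, on chromosome 8 from 127 to 128 Mb, held 138 peaks with a median background of 13.8, against 6.92 for the whole list. MYC, the oncogene inside that window, had a background of 51.7 and a pileup of 148 at its SW480 gene-end peak, and 9.55 and 30 in HCT116.

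Transfer RNA genes were among the bound noncoding genes. Of 443 tRNA genes 154 (34.8%, 30.5 to 39.3) had a gene-end peak in HCT116 and 54 (12.2%, 9.46 to 15.6) in SW480. A peak near several genes counts for each of them, so these are not counts of separate sites. The intervals here take genes as independent, and no random level was computed. Among the 368 tRNA genes at least 2 kb from any protein-coding gene the shares were 27.4% and 8.70%. Small nuclear RNA genes away from coding genes had 7.80% (4.41 to 13.4) and 4.96% (2.43 to 9.89). Long noncoding RNA genes away from coding genes had 5.25% and 2.89%, and such pseudogenes 0.665% and 0.381%. Counting also those near coding genes, long noncoding RNA genes had 14.01% and 7.55%, and pseudogenes 1.08% and 0.585%. The highest SW480 folds often lay far from gene ends. Of 39 SW480 peaks with a fold of at least 10, 13 were 50 kb or more from any gene end. They lay on chromosomes 4, 5, 16 and 20. In HCT116 1 of 556 was that far from a gene end, and it lay inside CACNA1A. Of these 13 peaks, 3 overlapped a HCT116 peak and 7 had the lowest background of the list. They were not filtered for repeated sequence, so mapping artifacts there were not told apart from binding.

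Fewer protein-coding genes had a gene-end peak in SW480 (4413) than in HCT116 (8791). Lower coverage of the SW480 ChIP library is argued against, because its genome-wide background level was 1.09 times that of HCT116. Scaling every HCT116 gene-end background by the ratio at strong shared genes left 7153 genes past the smallest p of the list, scaling the pileups left 8552, and scaling both left 6043. These numbers decide nothing, because the ratios come only from genes that kept a SW480 peak. A higher background and a lower pileup at SW480 gene ends both stay open, as does a biological difference between the lines, which was not tested.

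Chromosome 7 held a larger share of the SW480 list than of the HCT116 list. For a copy gain carried by ChIP and input alike, the median background of peaks away from gene ends was compared. On chromosome 7 in SW480 it was 0.750 (0.726 to 0.775) times that of the other chromosomes. This cannot decide the question, because background was read only at called peaks. The chromosome 7 median of 4.09 was also the lowest level of that list. A copy gain stays open. Weak peaks alone could not account for the larger share, since the ratio of shares was 1.89 (1.68 to 2.12) at a −log10 q of at least 5. With low backgrounds raised to the list median in each line the ratio was 2.20 (2.03 to 2.38). A background below that median was therefore not the whole cause. The raise reached only the median of called peaks, so a larger shortfall of background stays open. An input that under-samples this chromosome and a biological difference between the lines were not tested.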
